A study of Mus musculus with 1000 samples.

How the data were processed

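The study measured 3' RNA-seq of mouse brain, with the cerebellum removed, in third-generation offspring of males treated with the mutagen ENU. ENU (N-ethyl-N-nitrosourea) is a chemical that causes mostly single-base changes. By name, 999 libraries are generation 3 and 1 is generation 4. Per the labels' protocols, RNA from each animal received an in-line index, the libraries of 1 plate row were combined into a pool, and pools from 12 plates were sequenced together. GSNAP and the build GRCm38 are named in the submitters' processing notes; the version and the counting method were not given in the sources used here.

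The only processed file used here was a lookup table that the authors deposited. It lists 23231 library names and, for each, which of 3 data files holds its expression values. It has 0 columns of measurements, so no read count, expression level or sequencing depth was analysed here. Differential expression had been planned as count-based tests before the data were examined, on condition that a file used here held expression values. The planned contrasts were affected mice against the other mice of their pedigree, and affected Scarb2 mice against the unaffected pedigree. Gene lists for disease-associated microglia, homeostatic microglia and reactive astrocytes were also planned. Further lists covered oligodendrocytes, neurons, endothelium, choroid plexus, erythrocytes, T cells, lysosome and interferon response. A rule for the genes to be named was set as well. None of these tests was run, and no gene was named by that rule.

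What was computed rests on the library names, the sample labels and a gene annotation. Each library was matched to the lookup table by its exact name. Pedigree, mouse, plate, row, column and pool (the number after S) were read from the name, and groups from the labels for subset, candidate gene or pedigree, phenotype and genotype. Pools were also identified by plate and row. In 2 pedigrees, the plate columns of affected mice and of the other mice of the same pedigree, called pedigree-mates here, were compared. The names give a shared pedigree number and not the parents. The test was an exact two-sided permutation test of the difference in means, with Benjamini-Hochberg adjustment over the 2 tests. Shares of mice have exact Clopper-Pearson 95% intervals, which treat the related mice of a pedigree as independent draws. Mice without a label count as not labelled affected, so the shares and their intervals estimate no rate of a phenotype or genotype. The tests on plate columns were chosen after the labels had been read. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

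Gene positions and codons came from GENCODE mouse release M21, which is on GRCm38, the build named in the submitters' processing notes. Coding sequences were assembled from the annotated coding exons of each protein-coding transcript and translated. Every single-base change of the labelled codon was translated to find those giving the labelled amino acid change, with X read as a stop. These are readings of the reference sequence, and no genotype was called.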

Results

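The series holds 1000 brain RNA-seq libraries from 94 pedigrees of ENU-mutagenized mice, in which mice were screened for abnormal inflammatory states and candidate mutations were then sought by exome sequencing. Of these, 30 libraries from 3 pedigrees belonged to a labelled subset, and 970 libraries from 91 pedigrees lay outside it. The labels named Scarb2 I228F for 12 mice of 1 pedigree, Slc44a1 C487X for 6 mice of another, and called another pedigree of 12 mice unaffected. Expression values and sequencing depth were not analysed here, so no gene is described as higher or lower in any group.

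In the Scarb2 pedigree, 5 of 12 mice were labelled as affected, with the phenotype DAM and the genotype m/m (41.7%, exact 95% interval 15.2% to 72.3%). The labels do not spell out either abbreviation. The other 7 mice carried neither a phenotype nor a genotype label, so neither is known for them from the labels. The share of 5 of 12 therefore counts labels, and neither it nor its interval estimates a rate of affected mice. Scarb2 encodes LIMP-2, a lysosomal membrane protein that carries the enzyme glucocerebrosidase to lysosomes. The gene (ENSMUSG00000029426.8) lies on the minus strand of chromosome 5 from 92441314 to 92506833 in GRCm38. Its 1 annotated protein-coding transcript has 12 exons. The codon of the labelled residue lies in exon 5, at 92460062 to 92460064, and reads isoleucine in the reference, the amino acid that the label gives. Only 1 single-base change of this codon gives phenylalanine. It is A682T on the coding strand, counted from 1 at the first base of the start codon, and falls at position 92460064.

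In the Slc44a1 pedigree, 2 of 6 mice were labelled affected with the same phenotype and genotype (33.3%, exact 95% interval 4.3% to 77.7%). The other 4 carried neither label, so this share also counts labels only, and its interval bounds no rate. Slc44a1 encodes the choline transporter-like protein CTL1. The gene (ENSMUSG00000028412.17) lies on the plus strand of chromosome 4 from 53440413 to 53622478 in GRCm38. The labelled codon reads cysteine, as in the label, in 4 of its 5 annotated protein-coding transcripts, where it lies in exon 12 at 53545736 to 53545738. The coding sequence of the remaining transcript ends before this codon. The X in the label was read here as a stop codon. A single change, T1461A in the same numbering, turns the codon into a stop, at position 53545738.

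A comparison of affected mice with their pedigree-mates would ask which transcripts go with the affected label within a pedigree. It was not run. The pedigree-mates have no phenotype or genotype label, so they may include affected or m/m mice. Affected mice and their pedigree-mates shared a plate row, and therefore a library pool, in both pedigrees. All 12 Scarb2 libraries were in row H of plate neuro2175, with no other pedigree in that row. The 6 Slc44a1 libraries filled columns 1 to 6 of row A of the same plate, and 6 libraries of 1 pedigree outside the subset filled columns 7 to 12. The unaffected pedigree filled row A of plate neuro2181. A contrast of affected mice with the unaffected pedigree therefore compares different pedigrees, plates and pools at once, and these cannot be separated with 1 unaffected pedigree.

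Within the row, the 5 affected Scarb2 mice had a mean plate column of 6.20 ± 4.44 (SD, n = 5). Their 7 pedigree-mates had a mean of 6.71 ± 3.25 (SD, n = 7). The difference was smaller than the spread within either group (exact two-sided permutation p = 0.876, adjusted p = 0.876 over 2 tests). The 2 affected Slc44a1 mice occupied columns 5 and 6, with a mean of 5.50 ± 0.71 (SD, n = 2). All 4 pedigree-mates lay in columns 1 to 4, with a mean of 2.50 ± 1.29 (SD, n = 4). The exact permutation p was 0.133 (adjusted p = 0.266), which is the smallest that the 15 splits of 6 mice allow, so this design could not reach 0.05. Affected mice and pedigree-mates thus did not overlap in well column in the Slc44a1 pedigree. Columns followed mouse number in this row, so the affected mice, numbers 6 and 7, also had the highest mouse numbers.

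**Figure D1:**
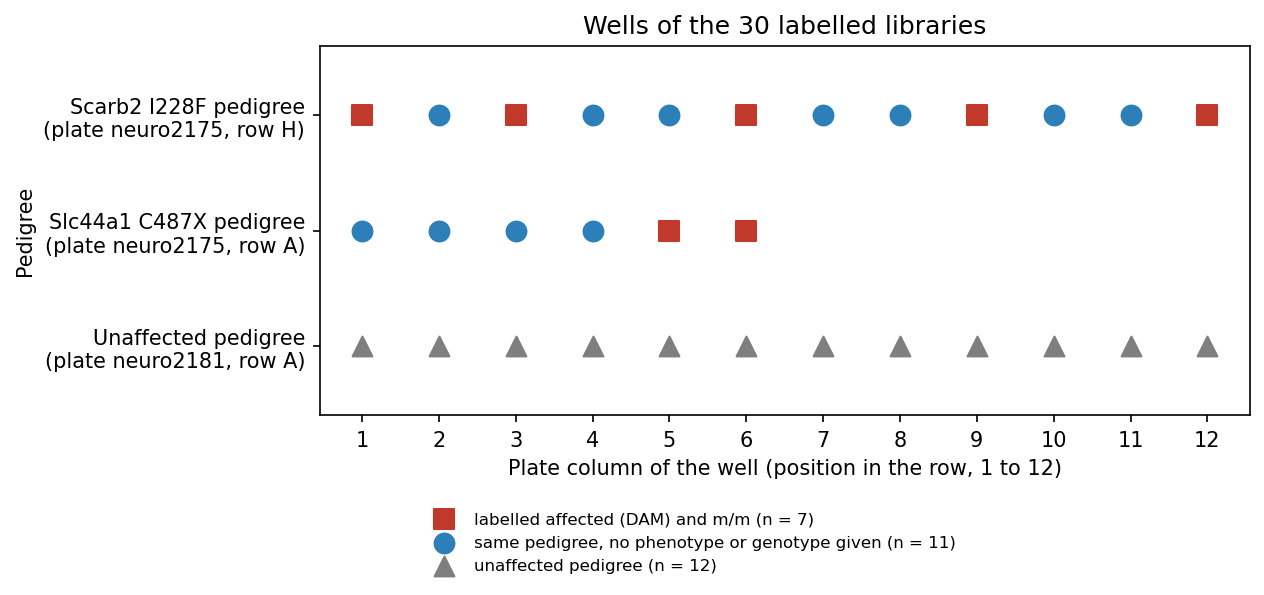
Wells of the 30 labelled libraries: the horizontal axis is the plate column (1 to 12) and each line is 1 pedigree in its plate row. Squares mark the 7 mice labelled affected and m/m, circles the 11 mice of the same pedigrees with neither label, and triangles the 12 mice of the unaffected pedigree. Affected mice are spread over columns 1 to 12 in the Scarb2 row and lie in columns 5 and 6 in the Slc44a1 row.

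Across the series, 71 pedigrees were represented by 12 mice, 2 by 11 and 21 by 6. The libraries came from 23 plates, grouped here by plate number into 2 runs of plates. Plates neuro2148 to neuro2159 held 62.3% of the libraries. Plates neuro2172 to neuro2183, of which 11 were present, held 37.7%. Each of the 94 pedigrees lay inside 1 pool. The names held 63 distinct pool numbers, 28 of them with more than 1 pedigree. Of these 28 numbers, 25 occurred in both runs and 3 in 1 run only. Counted by plate and row there were 88 pools, of which 82 held 1 pedigree and 6 held more than 1. In all 1000 names the pool number followed from the row and from the distance of the plate number from the first of its run. A difference between pedigrees in different pools is therefore also a difference between pools, whereas mice of 1 pedigree share theirs.

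All 1000 library names matched exactly 1 entry of the lookup table, and all of them pointed to data file 3. The labelled subset and the remaining libraries were thus assigned to the same processed file.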

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

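All 1000 libraries had a single match when the trailing number of the library name was left out, and when only pedigree, mouse and well were matched. Matching on pedigree and mouse alone, an alternative chosen after seeing the data, left all but 37 with a single match. The table holds no accessions, so matching on them was not run. Each of the 94 pedigrees lay inside 1 pool with either definition of a pool. The pool number followed from plate and row in all 1000 names. A pedigree inside 1 plate row therefore had to have 1 pool number, so this agreement is no independent check. The number of pools was 63 by pool number and 88 by plate and row, and the pools with more than 1 pedigree numbered 28 and 6. The 25 pool numbers that occur in both runs of plates each merge a pool of either run. The alternatives chosen beforehand for differential expression (another normalization, no filter on low counts, each replicate left out) were not run, because no expression values were analysed here. No paired analysis was possible because no expression values were analysed here and the replicate numbers only name the samples.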

Other observations

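For 37 of the 1000 libraries, from 21 pedigrees, the lookup table also held another library with the same pedigree and mouse name. All 37 were in the first run of plates (neuro2148 to neuro2159), and 0 belonged to the labelled subset. The other entries carried the plate names neuro2007rep (16 entries) or neuro2008rep (21 entries), and all 37 pointed to data file 1 instead of data file 3. The names alone do not say whether the same RNA was used again, and no expression values were compared.

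The name of 1 library, from pedigree ENU57040 (plate neuro2155, row E, column 6), reads generation 4, while the other 999 read generation 3. Its pedigree had 12 libraries in the series.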
